A study of Mus musculus with 19 samples.

How the data were processed

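The data were small RNA libraries of 19 to 24 nt from immunoprecipitated Ago2 of mouse brain at postnatal day 56, ligated to adaptors, amplified by PCR and sequenced on an Illumina Genome Analyzer II. Anti-Ago2 was used on whole neocortex and cerebellum, and anti-Myc on tissue in which Camk2a, Gad2, PV, SST or Purkinje cells carried tagged Ago2. Each library of Cerebellum, Neocortex and Camk2a came from 1 tissue, of Purkinje from 3 pooled tissues, and of Gad2, PV and SST from 4. Per the submitters' processing notes, reads were mapped with Bowtie to mm9, and the version of Bowtie is not given in the sources used here. Replicates are numbered in the titles, but separate animals are not stated.

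The deposited signal of 528 miRNA names was each library's read count scaled to a common total by the authors. Per the file headers the values are per 1000000 miRNA reads, but every column summed to 10000000, so values were divided by 10 to give RPM. Each column was 1 whole-number count per miRNA times a constant in all 19 libraries, from which the reads and the depth of each library were recovered. The highest depth was 11.6 times the lowest, and a floor of 3 reads stood at 0.211 to 2.439 RPM. Libraries held 445 to 510 detected miRNAs, and the 10 most abundant took 62.7% to 74.3% of reads. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 34.2 to 693 over 17 pairs.

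Samples were grouped by their titles into 7 groups. The design, written before the values were seen, asked for edgeR on counts and for limma on log2(value + 1) if the values were normalized. They were normalized, so limma 3.58.1 in R 4.3.3 was used with a trend, a pseudocount of 1 on the deposited scale and 1 fit of 7 group means. miRNAs with a value of at least 1 in 2 libraries were kept, which left 522. p-values were adjusted by Benjamini and Hochberg within each of 7 comparisons and called at an adjusted p under 0.05. Folds are 2 to the power of the fitted log2 change. A test of any difference between the 7 groups used the same fit. The TMM alternative divided each library by its edgeR 4.0.16 factor, which ran from 0.759 (Purkinje replicate 3) to 1.528 (SST replicate 1).

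Named miRNAs were called, had a mean of at least 100 RPM over the 2 groups and did not overlap between groups. The 10 of highest and the 10 of lowest log2 change were eligible, and for each list up to 4 called members with at least 10 RPM. Chance separates 3 libraries from 3 for 10% of miRNAs, and 2 from 2, as in PV against SST, for 33.3%. The 17 lists were fixed before the data were examined: neuronal, oligodendrocyte, vascular, blood and microglia, ependymal and choroid, astrocyte, hindbrain, the Dlk1-Dio3 domain, activity, the miR-17-92 clusters, the miR-183 cluster, let-7, miR-181, miR-29, miR-221 and miR-222, miR-15/16 and miR-30. They were tested with camera in limma at a preset correlation of 0.01 and again with an estimated one. The design had asked for log2 CPM with a prior of 2, and log2(value + 1) was used instead. p-values were adjusted over the 17 lists within a comparison. Members were also counted with p adjusted over the list alone. Medians were recomputed with members at 0 in 1 group placed at the 3-read floor of that group's shallowest library, and at 0 change where the other group lay under that floor. The hindbrain list held only the arms of miR-133b in these data. The neuronal list shares no member with the glial lists, and the astrocyte list shares members with the vascular, blood and miR-29 lists. The activity list and the Dlk1-Dio3 list share the arms of miR-134.

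For arm ratios, limma tested log2((minor arm + 0.5)/(major arm + 0.5)) of recovered reads for 155 hairpins with at least 20 summed reads in 2 libraries and a mean of at least 5 per arm. 6 sets of names had identical values in all libraries, and miR-199a-3p with miR-199b, miR-486 with miR-3107, and let-7a-1* with let-7c-2* were near-identical, so each such set counts 1 measurement more than once. Host genes and neighbours came from GENCODE M21 on GRCm38, matched by name. Mapping in the files used mm9, and no position was taken from either.

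The tests were tried on simulated data with 100 miRNAs changed per fold size in each comparison. Of 4-fold changes 84% were recovered for Cerebellum and Neocortex and for Purkinje and Cerebellum, 81% for Camk2a and Neocortex, and 75% for Gad2 and Neocortex. The share was 73% for Gad2 and Camk2a, 75% for PV and SST, and 79% for Purkinje and Gad2. Of 2-fold changes 54%, 49%, 57%, 46%, 48%, 31% and 49% were recovered in the same order. False calls made up 10.4%, 8.9%, 0%, 4%, 1.6%, 6.2% and 3.8% of calls. Of 50 changed arm ratios 74% were recovered with 2.6% of calls false. Here log ratios were simulated and not reads, so false calls from hairpins without minor-arm reads could not appear. All 3 shifted lists were recovered, with 0 of 12 unshifted lists called. The simulated miRNAs varied independently of each other, so false list calls from correlation between members could not appear. For the difference between 2 comparisons 68 of 100 changed miRNAs were recovered, with 3 calls among the 422 others.

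Alternatives tried were edgeR (TMM, relative log expression or total counts) and DESeq2 1.42.0 on recovered reads, pseudocounts of 0.1 and 10, no filter, only the 2 groups compared, a replicate block, leaving out each library, and TMM-divided values. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Raw reads were not analysed here, so read lengths, isomiRs and reads outside miRNAs were not used.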

Results

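MicroRNAs bound to Ago2 were profiled in the neocortex and cerebellum of mice at postnatal day 56, in whole tissue and in 5 classes of neurons that carried Myc-tagged Ago2. Ago2 was precipitated from whole neocortex and whole cerebellum with anti-Ago2 (n = 3 libraries each). Anti-Myc was used for Camk2a cells (n = 3), Gad2 cells (n = 3), PV cells (n = 2) and SST cells (n = 2) of the neocortex and for Purkinje cells (n = 3) of the cerebellum. Camk2a is a gene of excitatory neurons, Gad2 encodes an enzyme of GABA synthesis, and parvalbumin (PV) and somatostatin (SST) mark separate classes of GABAergic interneurons. The 19 libraries held between 1229834 miRNA reads (Cerebellum replicate 1) and 14249087 (Gad2 replicate 1). Depth ranged from 10309027 to 12824712 reads in Camk2a, 6983992 to 14249087 in Gad2, 2149027 to 10798553 in Neocortex and 10739153 to 11438142 in PV. It ranged from 1229834 to 3292571 reads in Cerebellum, 2063132 to 3378889 in Purkinje and 1278770 to 2457681 in SST. Levels are given as reads per 1000000 miRNA reads (RPM), as mean ± SD over the libraries of a group, so each is a share of the miRNA pool and not an amount per cell. Rankings are among called miRNAs with a mean of at least 100 RPM over the groups compared. All p-values measure only the spread between libraries of 1 to 4 tissues each, which may be partly technical, and separate animals are not stated for the replicates.

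The first question was which miRNAs made up each pool and how many differed between any of the 7 groups. miR-124, the main miRNA of neurons, was the most abundant in 6 groups, from 17.7% ± 3.74 of miRNA reads in Neocortex to 34.22% ± 2.91 in PV. In SST cells it held 15.4% ± 0.19 and miR-29b, which accumulates in mature neurons, came first with 18% ± 0.35. miR-29b held 2.65% ± 0.4 in Cerebellum against 12.69% ± 0.65 in Purkinje cells. miR-9, a miRNA of neural progenitors and neurons, held 12.17% ± 1.13 in Cerebellum and 5.21% ± 0.14 in Camk2a cells. miR-128, encoded in introns of R3hdm1 and Arpp21 (GENCODE M21, GRCm38), reached 15.35% ± 1.48 in Camk2a cells against 7.85% ± 1.21 in Neocortex. The let-7 family held 20.7% of the reads of Cerebellum and 16.03% of Neocortex, against 6.91% in PV, 7.38% in SST and 9.63% in Purkinje cells. miRNAs of the imprinted Dlk1-Dio3 domain held 2.06% ± 0.104 in Cerebellum and 9.84% ± 0.787 in SST. In limma, 455 of 522 tested miRNAs differed between any of the 7 groups at the threshold on the adjusted p. The nearest library in log2 level belonged to the same group for 18 of 19 libraries.

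**Figure D1:**
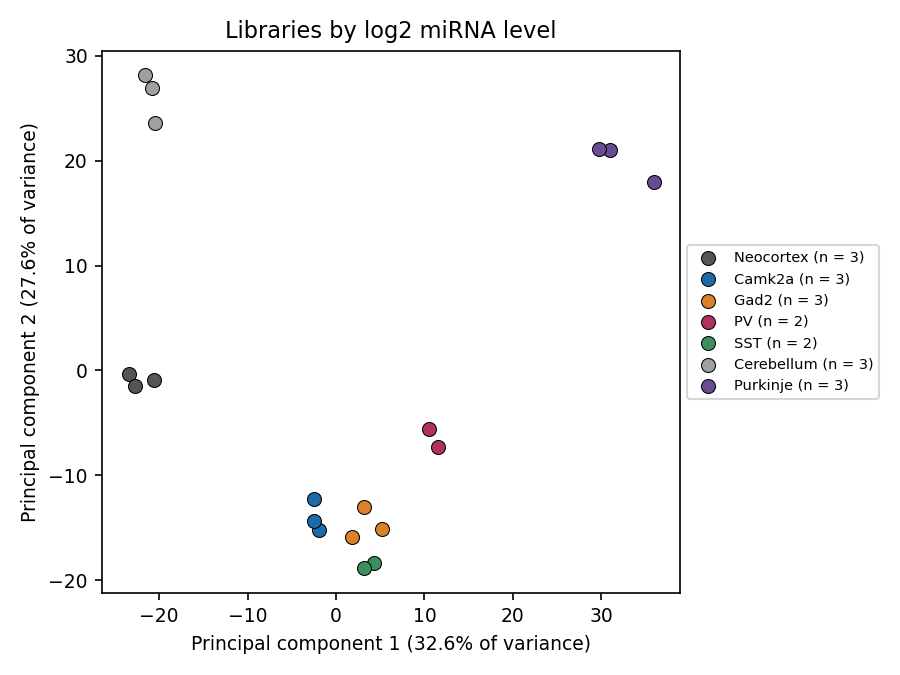
Principal components of the log2 levels of the tested miRNAs, with 1 point per library and 1 colour per group. The horizontal axis holds 32.6% and the vertical axis 27.6% of the variance, and libraries of the same group lie together.

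**Figure D2:**
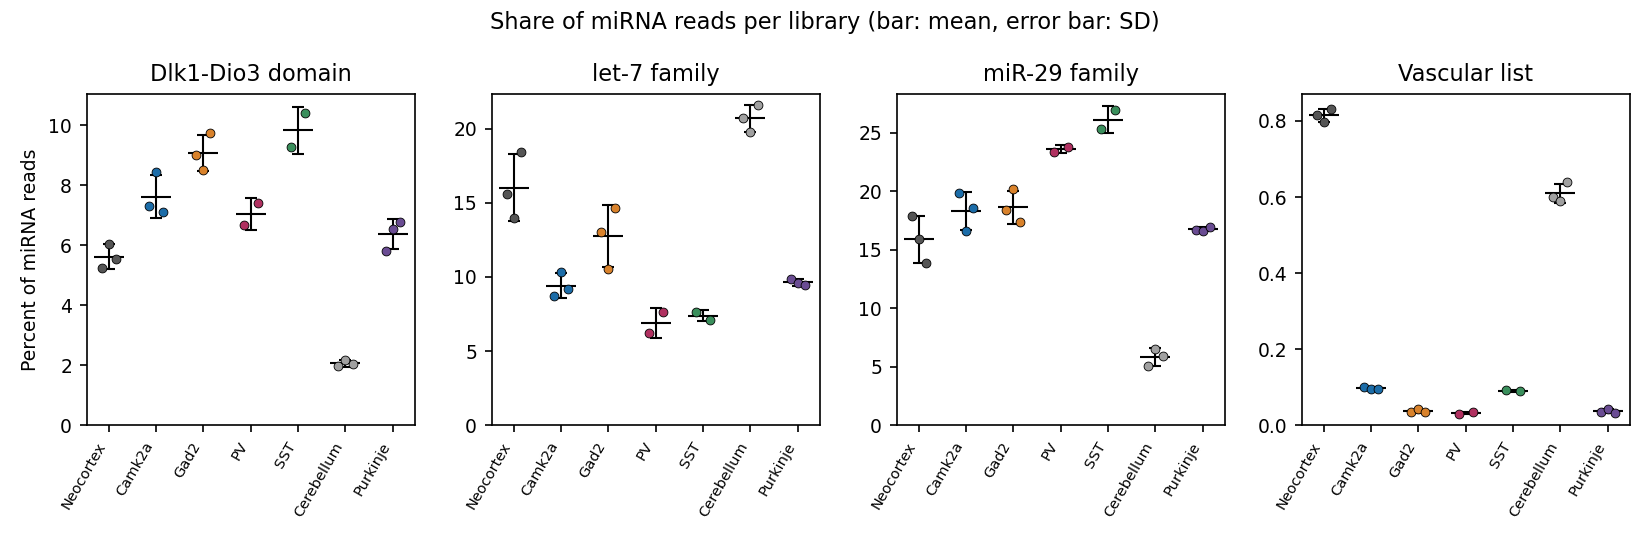
Share of miRNA reads (vertical axes, percent) held by the Dlk1-Dio3 domain, the let-7 family, the miR-29 family and the vascular list in each group (horizontal axes). Points are libraries, and bars with error bars are means with SD. The vascular list held 0.815% of reads in Neocortex and 0.036% in Gad2 cells.

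Whole cerebellum was compared with whole neocortex to ask which Ago2-bound miRNAs differ between the regions under the same antibody. Among miRNAs higher in cerebellum miR-133b came first, a miRNA first described in muscle that shares a long noncoding host with miR-206 (GENCODE M21, GRCm38). It was 42-fold higher in cerebellum (499 ± 57.4 against 12.1 ± 3.57 RPM, n = 3 each). Its level in cerebellum was close to that of miR-133a. miR-204 (25.1-fold, 1472 ± 239.7 against 58.4 ± 8.72 RPM), encoded in an intron of Trpm3 and abundant in choroid plexus, was also higher. So were the neighbouring miR-497 (15.8-fold, 4676 ± 415 against 298 ± 50.4 RPM) and miR-195 (12.1-fold, 4111 ± 177 against 341 ± 50.7 RPM). Higher in neocortex were miR-137 (19.6-fold, 436 ± 64.3 against 8794 ± 3032 RPM), a miRNA tied to synaptic genes, and miR-873 (26.4-fold, 20.5 ± 2.51 against 543 ± 25.97 RPM). The same held for miR-132* (15.9-fold, 131 ± 35.01 against 2092 ± 576 RPM), whose hairpin responds to neuronal activity, and for the intronic miR-551b (23.1-fold) and miR-708 (14.9-fold), in Egfem1 and Tenm4. Of the abundant neuronal miRNAs, miR-128 (4.07-fold, 19155 ± 1115 against 78483 ± 12056 RPM) was lower in cerebellum.

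Among the lists, the Dlk1-Dio3 domain lay lower in cerebellum, with 60 of 85 members lower, among them miR-409-3p (7.53-fold, 41.7 ± 2.47 against 315 ± 19.1 RPM), and miR-299* alone higher (median log2 change -1.34, camera adjusted p = 1.93e-07, adjusted p = 0.0825 with an estimated correlation). Of the ependymal and choroid list 5 of 6 members were higher, among them miR-34c (4.55-fold) and miR-204 (median 2.16, camera adjusted p = 0.0014, adjusted p = 0.0825 with an estimated correlation). Of the let-7 family 10 of 21 members were higher, among them let-7d* (2.37-fold), and miR-98 was lower (median 0.63, camera adjusted p = 0.00232, adjusted p = 0.201 with an estimated correlation). With TMM factors 14 of these members were higher and 0 lower. Of the miR-30 family 6 of 11 were higher, with miR-30b (3.01-fold, 4816 ± 302 against 1672 ± 631 RPM), at a median of 0.98 (camera adjusted p = 0.0186, adjusted p = 0.252 with an estimated correlation). The miR-29 family, whose members also stand in the astrocyte list, had 6 of 7 members lower, led by miR-29b (2.94-fold, 26511 ± 3973 against 78374 ± 15647 RPM) and miR-29a (2.71-fold), at a median of -1.14 (camera adjusted p = 0.0213, adjusted p = 0.0825 with an estimated correlation). Its list call was lost with TMM factors (adjusted p = 0.0544). In the miR-15/16 family 6 of 12 members were higher and 4 lower, the latter miR-16-1*, miR-195*, miR-322 and miR-322* (median 0.57, camera adjusted p = 0.048, adjusted p = 0.296 with an estimated correlation). That call was also lost with TMM factors (adjusted p = 0.0642) and, among other libraries, without Cerebellum replicate 3 (adjusted p = 0.0867). The hindbrain list consisted of the arms of miR-133b, both higher (median 3.77, or 2.7 with miR-133b*, at 0 in neocortex, set to the 3-read floor, camera adjusted p = 0.0213, adjusted p = 0.0825 with an estimated correlation). The counts of all 7 lists were the same adjusted over the list alone.

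In limma 290 of 522 miRNAs passed the threshold on the adjusted p, 102 higher and 188 lower in cerebellum, 232 of them by 2-fold or more (adjusted p = 1.38e-13 for miR-133b). The share of higher calls, 35.2%, became 46.4% with TMM-divided values, which moved the median log2 change of all miRNAs from -0.4 to -0.17. In edgeR with TMM factors on recovered reads the share stayed at 33.8%, with a median of -0.49. With relative log expression factors in edgeR the share was 46.2% (median -0.15), and in DESeq2 46.8% (median -0.03). The excess of lower calls therefore depended on scaling. The groups differed in strain background, and each library came from 1 tissue.

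Purkinje cells were compared with whole cerebellum to ask which miRNAs of the tissue these large GABAergic output neurons carry. miR-138 (21.3-fold, 44511 ± 8473 against 2102 ± 461 RPM), a miRNA that limits dendritic spine size, was the most strongly raised, and both minor arms of its hairpins were higher with it. miR-133b was 18.3-fold higher (9139.6 ± 1366 against 499 ± 57.4 RPM, n = 3 each) and miR-133a 17.8-fold. Counting both arms, these names held near-equal reads in Purkinje cells (72364 and 70141) and Cerebellum (3185 and 3176). They may therefore share reads, which was not tested. miR-433 (16.4-fold, 10867 ± 938 against 667 ± 105 RPM) and miR-341 (11.1-fold) of the Dlk1-Dio3 domain, and miR-770-5p (14-fold) of the Meg3 transcript within it, followed. miR-1, encoded beside miR-133a, was 9.59-fold higher and miR-708 12.1-fold. Most depleted were miR-135b (268-fold, 1.19 ± 0.730 against 311 ± 27.2 RPM) and miR-204 (187-fold, 8.27 ± 3.45 against 1472 ± 239.7 RPM). With a pseudocount of 10 the log2 change of miR-135b was -7.2 against -8.07. miR-497 (179-fold, 26.1 ± 2.64 against 4676 ± 415 RPM), miR-195 (118-fold, 35.2 ± 7.48 against 4111 ± 177 RPM) and miR-221 (104-fold, 5.74 ± 1.96 against 588 ± 71.6 RPM) were low in Purkinje cells. miR-143 (96.5-fold, 18.1 ± 0.946 against 1759 ± 36.6 RPM), a miRNA of smooth muscle, and miR-150 (128-fold, 3.64 ± 1.42 against 455 ± 36.4 RPM), a miRNA of lymphocytes, were lower as well. Of the neuronal miRNAs, miR-129-2-3p (125-fold, 79.98 ± 21.4 against 9812 ± 892 RPM), miR-137 (42.4-fold) and miR-218 (25.8-fold) were lower. miR-29b (4.82-fold, 126874 ± 6464 against 26511 ± 3973 RPM) of the astrocyte and miR-29 lists was higher.

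By list, 59 of 85 members of the Dlk1-Dio3 domain were higher and 4 lower, the latter miR-381, miR-381*, miR-487b and miR-544-5p (median log2 change 1.36, camera adjusted p = 5.92e-11, adjusted p = 0.0676 with an estimated correlation). With p adjusted over the list alone, 60 were higher and 5 lower. The vascular list had 6 of 7 members lower, with miR-126-3p (12.1-fold, 239 ± 20.7 against 2882 ± 161 RPM) beside miR-143 (median -3.6, -3 with members at 0 set to the floor, camera adjusted p = 0.0014, adjusted p = 0.0676 with an estimated correlation). All 6 ependymal and choroid members were lower (median -5.18, -3.95 at the floor, camera adjusted p = 0.00112, adjusted p = 0.102 with an estimated correlation). In the miR-15/16 family 10 of 12 were lower, with miR-15a (23-fold), at a median of -3.29 (camera adjusted p = 0.00112, adjusted p = 0.122 with an estimated correlation). Both arms of miR-221 and miR-222 were lower (median -6.1, -4.17 at the floor, camera adjusted p = 0.0318, adjusted p = 0.204 with an estimated correlation). The let-7 family had 16 of 21 members lower, with let-7c (4.47-fold, 14865 ± 1964 against 66086 ± 3702 RPM), while let-7i and miR-98 were higher (median -1.32, -1.28 at the floor, camera adjusted p = 0.0318, adjusted p = 0.338 with an estimated correlation). Of the blood and microglia list 9 of 14 were lower, with miR-451 (52.6-fold, 40.2 ± 7.05 against 2108 ± 279 RPM), and miR-486, an erythroid miRNA, was higher (median -3.29, -2.69 at the floor, camera adjusted p = 0.0369, adjusted p = 0.338 with an estimated correlation). The neuronal list had 16 of 25 members lower and 4 higher, 3 of these from miR-138 hairpins (median -1.24, -1.1 at the floor, camera adjusted p = 0.044, adjusted p = 0.122 with an estimated correlation). That call was lost without Purkinje replicate 2 (adjusted p = 0.063) or Cerebellum replicate 3 (adjusted p = 0.0521). The 2 arms of miR-133b passed as the hindbrain list (median 4.6, camera adjusted p = 0.0477, adjusted p = 0.123 with an estimated correlation, and adjusted p = 0.058 without Purkinje replicate 2, 1 of several such losses). These 8 lists kept their counts when adjusted over the list alone.

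The limma test passed 358 of 522 miRNAs, 163 higher and 195 lower in Purkinje cells, and 312 of them differed by 2-fold or more (adjusted p = 1.41e-12 for miR-138). The antibody and the number of pooled tissues changed together with the cell type, so none of these differences can be assigned to the cells alone.

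**Figure D3:**
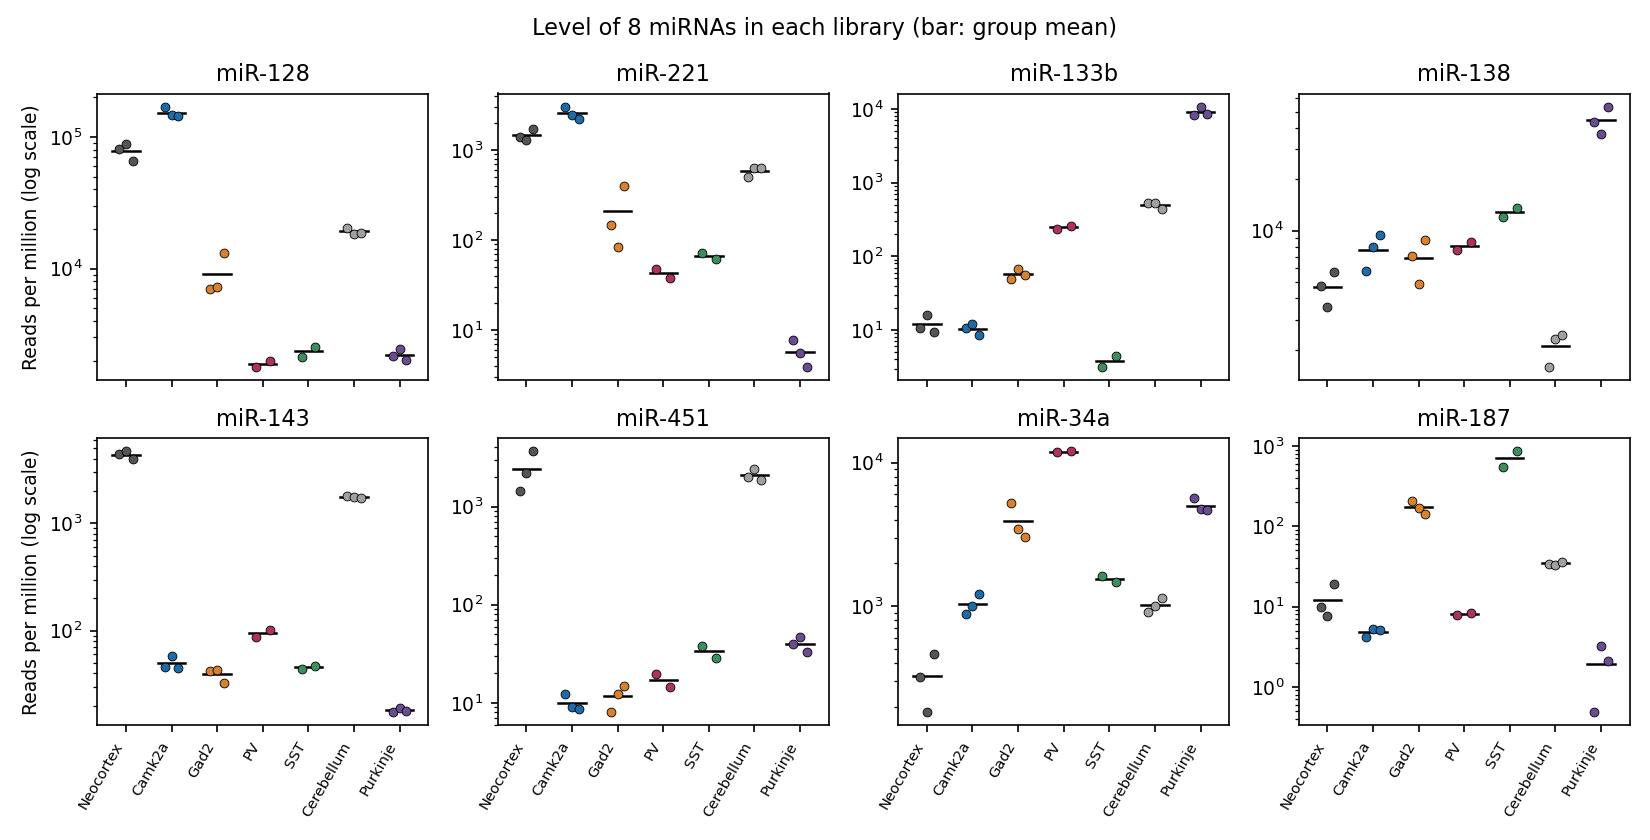
Levels of 8 miRNAs in the 19 libraries, in RPM on log axes, by group. Points are libraries and bars are group means. miR-128 was lowest in Purkinje, PV, SST and Gad2 cells, and miR-133b was highest in Purkinje cells.

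Camk2a cells were compared with whole neocortex to ask which miRNAs of the tissue excitatory neurons carry. The largest losses were miR-451 (226-fold, 10.02 ± 2.08 against 2431 ± 1126 RPM), a miRNA of red blood cells, and miR-143 (88-fold, 49.8 ± 7.34 against 4369 ± 359 RPM) of smooth muscle (n = 3 each). miR-338-3p (3.81-fold, 658 ± 73.8 against 2549.8 ± 603 RPM) of oligodendrocytes, encoded in an intron of Aatk, and miR-126-3p (3.8-fold, 689 ± 30.4 against 2656 ± 571 RPM) of endothelium were lower too. Gains were smaller. miR-431 (5.85-fold, 192 ± 34.8 against 32.7 ± 5.42 RPM) of the Dlk1-Dio3 domain came first, followed by miR-129-5p (3.85-fold, 990.2 ± 92.95 against 264 ± 78.7 RPM), miR-212-3p (3.5-fold, 248 ± 42.5 against 70.3 ± 2.37 RPM) and miR-34a (3.39-fold). miR-24 (2.82-fold, 7502 ± 1106 against 2754 ± 876 RPM) was higher as well, although its name stands in the astrocyte list. The abundant miR-218 (2.24-fold, 6004 ± 619.6 against 2711 ± 509 RPM), in introns of Slit2 and Slit3, was also higher in Camk2a cells.

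All 7 vascular members were lower (median log2 change -3.09, camera adjusted p = 1.38e-05, adjusted p = 0.0187 with an estimated correlation). This list call and its counterpart in Gad2 cells were the only ones of all comparisons that held with an estimated correlation. Of the blood and microglia list 10 of 14 members were lower, with miR-142-5p (208-fold) at 0.384 ± 0.187 against 95.8 ± 11.8 RPM, whose log2 change moved from -7.7 to -6.13 with a pseudocount of 10. Only miR-486 was higher (median -2.92, -2.22 with members at 0 set to the floor, camera adjusted p = 4.89e-05, adjusted p = 0.0934 with an estimated correlation). The oligodendrocyte list had 4 of 5 members lower, with miR-219-5p (11.9-fold, 1.88 ± 0.430 against 23.3 ± 4.11 RPM), at a median of -1.93 (camera adjusted p = 0.00258, adjusted p = 0.0778 with an estimated correlation). The Dlk1-Dio3 domain had 30 of 85 members higher and 5 lower, namely miR-376b*, miR-376c, miR-412-5p, miR-541 and miR-544-5p (median 0.44, camera adjusted p = 2.58e-06, adjusted p = 0.0934 with an estimated correlation). With TMM factors 37 of its members were higher and 1 lower. Of the activity list 4 of 8 members were higher, with miR-132 (1.85-fold) and miR-134 (2.42-fold) beside miR-212-3p (median 0.88, camera adjusted p = 0.0105, adjusted p = 0.0778 with an estimated correlation). The miR-181 family had 5 of 10 members lower, with miR-181a (2.48-fold, 5311 ± 851 against 13374 ± 3781 RPM), at a median of -1.16 (-0.89 at the floor, camera adjusted p = 0.0324, adjusted p = 0.449 with an estimated correlation). Its call was lost with TMM factors (adjusted p = 0.0561) and without Neocortex replicate 1 (adjusted p = 0.0517). Adjusted over the list alone, 11 blood and microglia members and 6 miR-181 members were lower, and the other counts stayed the same.

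By limma 234 of 522 miRNAs differed, 88 higher and 146 lower in Camk2a cells, 166 of them by 2-fold or more (adjusted p = 2.33e-17 for miR-143). With TMM-divided values the share of higher calls went from 37.6% to 50.9% and the median log2 change of all miRNAs from -0.25 to -0.04. In edgeR with TMM factors on recovered reads the share was 45.2%. The antibody changed with the group, while strain and pooling were the same.

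Gad2 cells were compared with whole neocortex to ask the same of GABAergic neurons. miR-34a (12.5-fold, 3902 ± 1173 against 324 ± 142 RPM), a target of p53 signalling, had the largest gain (n = 3 each), ahead of miR-433 (4.63-fold, 4996 ± 952 against 1081 ± 209 RPM), miR-134 (4.16-fold, 339 ± 64.00 against 81.7 ± 17.2 RPM) and miR-133a (4.3-fold). The blood and smooth muscle miRNAs miR-451 (196-fold) and miR-143 (112-fold) had the largest losses. miR-126-3p (11.5-fold, 229 ± 18.7 against 2656 ± 571 RPM) of endothelium was lower too. Losses also reached abundant miRNAs of neurons. miR-128 (8.92-fold, 9122 ± 3497 against 78483 ± 12056 RPM) was lower, and so were miR-135a (8.6-fold) and miR-222 (8.77-fold, 76.8 ± 41.8 against 615 ± 87.5 RPM). miR-221 was 8.58-fold lower (210.2 ± 167 against 1470.1 ± 208 RPM), with a log2 change of -3.72 without Gad2 replicate 3, which held the most miR-221 of its group.

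The vascular list had 6 of 7 members lower (median log2 change -2.52, -1.4 with the member at 0 set to the floor, camera adjusted p = 0.000192, adjusted p = 0.0462 with an estimated correlation). The Dlk1-Dio3 domain had 34 of 85 members higher, with miR-431 (4.06-fold), and miR-376c, miR-494 and miR-541 lower (median 0.6, camera adjusted p = 2.39e-07, adjusted p = 0.101 with an estimated correlation). With TMM factors 42 of its members were higher and 1 lower. In the blood and microglia list 9 of 14 were lower, with miR-486 higher (median -3.25, camera adjusted p = 0.000717, adjusted p = 0.141 with an estimated correlation). In the miR-17-92 clusters 10 of 16 were lower, with miR-20a (6.28-fold, 44.5 ± 17.8 against 275 ± 80.3 RPM), at a median of -1.79 (-1.56 at the floor, camera adjusted p = 0.000847, adjusted p = 0.101 with an estimated correlation). The oligodendrocyte list had 4 of 5 lower, with miR-338-3p (3.78-fold), at a median of -1.92 (camera adjusted p = 0.00559, adjusted p = 0.101 with an estimated correlation). Both arms of miR-221 and miR-222 were lower (median -3.32, camera adjusted p = 0.0075, adjusted p = 0.141 with an estimated correlation), as were 5 of 12 miR-15/16 members, with miR-15b (6.64-fold, 16.1 ± 3.69 against 108 ± 30.9 RPM), at a median of -0.76 (camera adjusted p = 0.00909, adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, 37 Dlk1-Dio3 members were higher, 10 blood and microglia members were lower, and the other counts stayed the same. The limma test passed 235 of 522 miRNAs, 108 higher and 127 lower, 179 of them by 2-fold or more (adjusted p = 3.64e-10 for miR-34a). With TMM-divided values 127 were higher and 112 lower, whereas edgeR with TMM factors on recovered reads gave 113 higher and 152 lower. The prevailing direction therefore depended on the method. Antibody, strain and the number of pooled tissues all changed with the group.

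Gad2 cells were compared with Camk2a cells to ask how inhibitory and excitatory neurons of the neocortex differ under the same antibody. miR-128 (17.5-fold, 9122 ± 3497 against 153461 ± 14821 RPM) showed the largest difference, lower in Gad2 cells (n = 3 each). miR-221 (15-fold, 210.2 ± 167 against 2571 ± 446 RPM) and miR-222 (10.3-fold, 76.8 ± 41.8 against 726 ± 108 RPM) were lower as well, and without Gad2 replicate 3 the log2 change of miR-221 was -4.52 against -3.9. miR-132 (3.5-fold, 205 ± 44.6 against 715 ± 117 RPM), miR-132* (4.74-fold) and miR-27a (4.1-fold) followed. Higher in Gad2 cells were miR-384-5p (5.64-fold, 3581 ± 362 against 655 ± 200.1 RPM), a miRNA of synaptic plasticity, miR-181a (3.77-fold, 19961 ± 2457 against 5311 ± 851 RPM) and miR-34a (3.7-fold). miR-30e (2.95-fold) and miR-133a (3.09-fold) were higher too.

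In the miR-17-92 clusters 10 of 16 members were lower in Gad2 cells, with miR-92a (11.9-fold) and miR-20a (3.52-fold), at a median log2 change of -1.39 (-1.31 with members at 0 set to the floor, camera adjusted p = 0.00021, adjusted p = 0.086 with an estimated correlation). All 4 arms of miR-221 and miR-222 were lower (median -3.64, camera adjusted p = 0.00193, adjusted p = 0.137 with an estimated correlation). Of the neuronal list 11 of 25 members were lower, with miR-129-5p (3.08-fold, 331 ± 107 against 990.2 ± 92.95 RPM) beside miR-128, whereas miR-9 and miR-9* were higher (median -0.33, camera adjusted p = 0.00844, adjusted p = 0.086 with an estimated correlation). Neither miR-9 arm was called with TMM factors, and 12 neuronal members were then lower. Of the miR-181 family 6 of 10 members were higher, with miR-181b (2.68-fold) and miR-181c (2.48-fold), at a median of 0.77 (camera adjusted p = 0.00844, adjusted p = 0.249 with an estimated correlation). Adjusted over the list alone, 3 neuronal members were higher and the other counts stayed the same. By limma 199 of 522 miRNAs differed, 112 higher and 87 lower in Gad2 cells, 140 of them by 2-fold or more (adjusted p = 2.54e-12 for miR-128). With TMM-divided values 95 were higher and 96 lower, and edgeR with TMM factors on recovered reads gave 105 higher and 125 lower. Strain and the number of pooled tissues differed between these groups.

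PV cells were compared with SST cells, the only comparison matched in antibody, strain and pooling, to ask how 2 interneuron classes differ. miR-133b was 64-fold higher in PV cells (246 ± 17.2 against 3.80 ± 0.953 RPM, n = 2 each). miR-133a (33.1-fold, 1741 ± 441 against 51.6 ± 1.08 RPM) and miR-1 (26.1-fold, 2086 ± 336 against 79.4 ± 8.20 RPM), which are encoded side by side, were higher with it, and so were miR-34a (7.68-fold, 11877 ± 147 against 1547 ± 103 RPM) and miR-218 (5.28-fold, 6502 ± 81.1 against 1245 ± 270.2 RPM). miR-124 was 2.22-fold higher. SST cells held more of miR-187 (85.1-fold, 7.97 ± 0.346 against 703 ± 215 RPM), miR-551b (44.4-fold, 15.5 ± 0.330 against 692 ± 18.9 RPM) and miR-137 (11.6-fold, 229 ± 23.8 against 2675 ± 447 RPM). miR-7a (15.2-fold, 69.3 ± 12.98 against 1064 ± 265 RPM), a miRNA of neuroendocrine cells, and miR-7b (16.1-fold) were also higher in SST cells, as were miR-31 (15.4-fold), miR-873 (7.03-fold) and miR-139-5p (6.1-fold), the last in an intron of Pde2a. The single tested member of the miR-183 cluster list, miR-182, stood at 90.2 RPM in PV replicate 1 and at 2.7 in PV replicate 2.

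Of the activity list 5 of 8 members were lower in PV cells, with miR-132 (4.6-fold, 148 ± 10.4 against 697 ± 205 RPM) and miR-188-5p (6.58-fold), at a median log2 change of -1.64 (camera adjusted p = 0.0477, adjusted p = 0.119 with an estimated correlation). The call was lost in 9 of 19 fits without 1 library, as without SST replicate 2 (adjusted p = 0.153) or PV replicate 2 (adjusted p = 0.0546). miR-133b carried the hindbrain list, whose other arm was at 0 in both groups (median 3, camera adjusted p = 0.0336, adjusted p = 0.119 with an estimated correlation, and adjusted p = 0.0543 with TMM factors). The miR-30 family did not pass (camera adjusted p = 0.121, and 0.0302 with TMM factors). Both called lists kept their counts when adjusted over the list alone. The limma test passed 152 of 522 miRNAs, 21 higher and 131 lower in PV cells, 118 of them by 2-fold or more (adjusted p = 1.28e-08 for miR-187). With TMM factors 118 passed, 61 higher and 57 lower, so the share of higher calls went from 13.8% to 51.7%. The median log2 change of all miRNAs went from -0.42 to 0.11, and log2 changes shifted upwards, for miR-187 from -6.41 to -5.78. Without PV replicate 1, 94 miRNAs passed, and miR-378 and miR-129-1-3p lost their calls without SST replicate 1 (adjusted p = 0.139 and 0.208).

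Purkinje cells were compared with neocortical Gad2 cells to ask how GABAergic neurons of the 2 regions differ under the same antibody. miR-133b was 161-fold higher in Purkinje cells (9139.6 ± 1366 against 56.8 ± 8.95 RPM, n = 3 each) and miR-133a 22.2-fold. Their near-equal reads in Purkinje cells leave open that both names count the same reads. miR-138 (6.55-fold, 44511 ± 8473 against 6907 ± 1955 RPM), let-7i (5.01-fold, 16399 ± 909 against 3343 ± 865 RPM) and miR-338-3p (4.44-fold, 2946 ± 287 against 662 ± 35.8 RPM) were higher, the last a miRNA of oligodendrocytes. miR-486 was 14.1-fold higher, with miR-3107, its near-identical name, beside it. Intronic miR-151-5p of Ptk2 was 9.09-fold higher. Lower in Purkinje cells were miR-137 (211-fold, 10.2 ± 1.94 against 2221 ± 680.2 RPM), miR-335-5p (56-fold, 30.8 ± 0.664 against 1779 ± 539 RPM) of the imprinted gene Mest, miR-129-2-3p (44.3-fold, 79.98 ± 21.4 against 3484 ± 449 RPM) and miR-153 (20-fold, 104 ± 8.62 against 2098 ± 300.7 RPM) of Ptprn2. miR-149 (16.2-fold) and miR-218 (14.7-fold) followed. miR-221 was 30.3-fold lower, with a log2 change of -4.31 without Gad2 replicate 3.

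The 2 arms of miR-133b made up the hindbrain list (median log2 change 7.23, 6.19 with miR-133b*, at 0 in Gad2 cells, set to the floor, camera adjusted p = 0.0148, adjusted p = 0.0955 with an estimated correlation). All 6 ependymal and choroid members were lower, with miR-34c (13.6-fold, 4.37 ± 0.365 against 61.3 ± 11.1 RPM) and miR-204 (2.53-fold, 8.27 ± 3.45 against 19.96 ± 4.76 RPM), at a median of -3.64 (-1.59 at the floor, camera adjusted p = 0.0248, adjusted p = 0.21 with an estimated correlation). All 4 arms of miR-221 and miR-222 were lower (camera adjusted p = 0.0558, and 0.0318 with TMM factors). Counts did not change when adjusted over the list alone. By limma 287 of 522 miRNAs differed, 107 higher and 180 lower in Purkinje cells, 236 of them by 2-fold or more (adjusted p = 3.82e-16 for miR-137). TMM factors moved the median log2 change of all miRNAs from -0.31 to -0.16, with 138 higher and 167 lower. edgeR with TMM factors gave 146 higher and 158 lower, and DESeq2 152 and 148, so the excess of lower calls depended on scaling. Tissue, strain and the number of pooled tissues changed with the group.

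Across the 7 comparisons 37 of 119 list tests passed, 13 with the list higher and 24 with it lower, and 2 passed with an estimated correlation. Of 100 regroupings of the libraries 5 gave as many, the real one included, so chance is not excluded for their number. The astrocyte list passed in none, with the smallest camera adjusted p, 0.0554, in Gad2 cells against Neocortex. miR-182, alone in the miR-183 cluster list, passed in none as a list, with camera adjusted p = 0.2 in PV against SST. Camera compares a list with the remaining miRNAs, so its sign and that of the median can differ where most miRNAs lie below 0. This was so for none of the lists that passed. Among the rest it occurred, for instance, for the oligodendrocyte list in cerebellum against neocortex (median -0.43, test higher) and the neuronal list in PV against SST (median -0.31, test higher).

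The last question was whether the share of the arms of 1 hairpin differed between groups, which does not depend on scaling between libraries. In limma 110 of 155 hairpins passed, and the 5 of smallest p were miR-133a, miR-296, miR-99a, miR-486 and miR-133b. Some hairpin names pool several precursors, such as miR-133a with 2 and miR-9 with 3. There a different mix of precursors could give the same result. For miR-296, a hairpin of low level here, the 5p arm held 96.67% ± 5.77 of reads in Purkinje cells (22 summed reads) and 79.4% ± 4.89 in Cerebellum (106 reads). It held 40.9% ± 4.59 in Neocortex, 23.09% ± 2.26 in Camk2a and 3.65% ± 2.04 in SST cells (limma adjusted p = 2.14e-08). The minor arm of miR-99a, a relative of miR-100 that lies beside let-7c, held 6.05% ± 0.18 in PV and 3.04% ± 0.28 in SST cells. It held 0.67% ± 0.04 in Neocortex (limma adjusted p = 4.44e-07). The minor arm of miR-486 held 11.74% ± 1.35 in Neocortex and at most 2.01% elsewhere (adjusted p = 6.22e-07). The minor arm of miR-133a held 1.23% ± 0.36 of reads in Camk2a, 0.59% ± 0.22 in Gad2, 0.57% ± 0.04 in PV and 0.01% in Purkinje cells (limma adjusted p = 2.14e-08). Its share in Purkinje cells would be lowered if major-arm reads of miR-133b were also counted as miR-133a, which was not tested. The minor arm of miR-133b held 0.16% ± 0.05 of 72364 summed reads in Purkinje cells and 0.12% ± 0.13 of 3185 in Cerebellum. It had no read among 5470 in PV, 1576 in Gad2, 354 in Camk2a, 190 in Neocortex and 15 in SST cells. Without minor reads the tested ratio follows depth, so the p of miR-133b does not show a difference in share. The 110 are therefore passing ratios, not all of them shown differences in share.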

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

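The difference between cell types was tested for the named miRNAs of both comparisons after those had been seen, and the tests on the Dlk1-Dio3, oligodendrocyte and PV patterns were also chosen after the result was seen.

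Purkinje and Camk2a cells departed from their own tissues in part alike and in part differently. The log2 change of Purkinje against Cerebellum less that of Camk2a against Neocortex was tested in limma, and 247 of 522 miRNAs passed (245 with TMM factors). Of the miRNAs called in both comparisons, 53 were higher in both cell types (27.5 expected of independent calls), 94 lower in both (54.5 expected) and 35 opposite. The 35 opposite ones were fewer than independent calls would give. Anti-Myc replaced anti-Ago2 in both comparisons, so the alike changes cannot be assigned to the cells alone. Of 38 miRNAs named in either comparison 30 differed, and naming by extreme change favours a difference. The Purkinje change was the higher for miR-133b (4.38), miR-1 (3.83), miR-138 (3.68), miR-133a (3.67), miR-433 (3.24), miR-138-2* (3.23) and miR-770-5p (2.85). The same held for miR-708* (2.76), miR-708 (2.49), miR-451 (2.11), miR-341 (1.95), miR-338-3p (1.75), miR-541 (1.59) and miR-100 (0.45), of which miR-100 lost its call with TMM factors (0.26, limma adjusted p = 0.399). It was the lower for miR-204 (-7.74), miR-497 (-7.63), miR-135b (-7.56), miR-221 (-7.51), miR-129-2-3p (-7.44), miR-195 (-7.31), miR-92b (-6.77), miR-135a (-4.48) and miR-129-5p (-4.02). Smaller differences of that sign were those of miR-130a (-3.27), miR-339-5p (-2.48), miR-24 (-1.69), miR-126-3p (-1.67), miR-126-5p (-1.53), miR-26b (-1.45) and miR-99a (-1.14).

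By list, the median difference was 0.75 for the Dlk1-Dio3 domain (camera adjusted p = 0.00062, adjusted p = 0.231 with an estimated correlation). It was 1.75 for the oligodendrocyte list (camera adjusted p = 0.0378, adjusted p = 0.204 with an estimated correlation). The ependymal and choroid list differed by -3.88 (camera adjusted p = 0.000579, adjusted p = 0.085 with an estimated correlation) and the neuronal list by -1.38 (camera adjusted p = 0.00992, adjusted p = 0.085 with an estimated correlation). For miR-221 and miR-222 the difference was -5.24 (camera adjusted p = 0.00992, adjusted p = 0.204 with an estimated correlation), and for the miR-15/16 family -1.66 (camera adjusted p = 0.034, adjusted p = 0.266 with an estimated correlation). Shuffling the 12 libraries among the 4 groups gave as many calls in 1 of 100 regroupings, the real one. Such shuffling also breaks up the differences between tissues and cell types. It therefore cannot decide whether the 2 changes were equal. The highest other count, 150, shows that regroupings which keep part of the grouping also call many.

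The Dlk1-Dio3 list lay higher in Purkinje, Camk2a and Gad2 cells than in their tissues, where the antibody changed as well (adjusted p = 0.0676, 0.0934 and 0.101 with an estimated correlation, so camera passed only with its preset one). If an antibody effect of equal size in both tissues were the whole cause, the rise of the list mean would match in Purkinje and Camk2a cells. The rise differed by 0.88 (SE 0.21), which argues against that. An antibody effect that varies with tissue was not tested, since no cell type had both antibodies. Scaling shifts all miRNAs of a library alike, but the list mean rose over that of all other miRNAs by at least 1.03 (SE 0.06), which scaling cannot give. The list exceeded the neuronal list by 0.34 (SE 0.11) in Camk2a cells, less than the spread of the neuronal members (SD 0.98), so this does not decide on removal of other cells' RNA. The excess was 1.36 (SE 0.1, SD 1.16) in Gad2 and 2.61 (SE 0.24, SD 2.96) in Purkinje cells. In Gad2 cells the excess was over the SD and the neuronal list mean fell (log2 change -0.74). This argues against an equal rise of all neuronal miRNAs in Gad2 cells. In Purkinje cells the neuronal list mean fell too (-1.26), but the excess lay under the SD. As in Camk2a cells, it does not decide there. Removal of other cells' RNA, an antibody effect that is partial or varies with tissue, and a difference between cell types remain open.

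Of the oligodendrocyte list only miR-338-5p was called lower in Purkinje cells than in Cerebellum, whereas 4 of 5 members fell in Camk2a and Gad2 cells (adjusted p = 0.0778 and 0.101 with an estimated correlation, so these list calls were lost). The call of miR-338-5p was lost in edgeR with TMM factors (log2 change -0.35, edgeR adjusted p = 0.123). miR-219-3p stood near the 3-read floor in Cerebellum and could hardly fall there, so these counts are not alike. Carry-over of whole cerebellar RNA would keep vascular and blood miRNAs alike, but the median share of the cerebellar level kept was 0.0768 for those over 1000 RPM (miR-126-3p 0.0828, miR-143 0.0103, miR-451 0.0191), against 0.884 for miR-338-3p and 0.672 (SD 0.061) for miR-338-5p. Only miR-21, at 0.59 (SD 0.17), was kept about as carry-over would have it, so the others exclude carry-over as the whole cause and a smaller part remains open. RNA of oligodendrocyte-lineage cells would keep the ratio of miR-219-5p to miR-338-3p, which changed by 0.51 (SE 0.46) here, by -1.64 (SE 0.18) in Camk2a and by -0.73 (SE 0.23) in Gad2 cells. The SE of 0.46 allows a change of over 2-fold, so such RNA and expression by Purkinje cells, which was not tested, cannot be told apart.

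Lower calls prevailed in PV against SST cells. The share of higher calls was 51.7% with TMM factors, but these centre the log changes whatever the cause, so an effect of scaling to total miRNA reads and a true prevalence of lower levels cannot be told apart. Counting error from the lower depth of the SST libraries is excluded as the cause, since with PV reads thinned to that depth the share was 13.3%. Thinning does not reproduce PCR duplication, so other effects of shallow libraries were not tested.

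For each comparison of 3 and 3 libraries, the real split was the only 1 of 10 with as many calls, and 10 splits are too few for a share under 0.05. The highest other split called 2 miRNAs for Cerebellum and Neocortex, 1 for Purkinje and Cerebellum, 0 for Camk2a and Neocortex, 4 for Gad2 and Neocortex, 0 for Gad2 and Camk2a, and 1 for Purkinje and Gad2. These splits follow a fixed rule and were not chosen by their result. For the difference between any groups, 1 of 100 regroupings called as many as the real 455 (highest other 10), and for arm ratios 1 of 100 (highest other 2). For the list tests 5 of 100 regroupings gave as many calls as the real 37, with a highest other of 46, so chance is not excluded for their number.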

How the results depend on the processing

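The added alternatives (edgeR with TMM factors on recovered reads, TMM-divided values, a mean of at least 10 RPM, and list tests with TMM factors or without each library) were chosen after the result was seen. Of 190 alternative counts 188 stayed within 1.5 times the main count and 2 did not. PV against SST ranged from 94 (without PV replicate 1) to 130 calls when 1 library was left out, against 152, with the lone library left in a group assumed to vary like the other groups. The list tests passed 2 of 119 with an estimated correlation against 37. The cause was not tested in either case. These counts compare numbers of calls and not which miRNAs were called. For PV against SST, 78 of the 152 main calls were shared with TMM-divided values, 89 with edgeR and TMM factors, and 91 with DESeq2.

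Of the calls on named miRNAs 6776 were kept, 190 were lost (adjusted p over the threshold) and 0 reversed. Of the log2 changes 119 moved by more than 1.5-fold, 46 of them with TMM-divided values and 25 with a pseudocount of 10, the latter among miRNAs near the floor. Leaving out 1 library gave 252 to 270 calls for Cerebellum against Neocortex, 339 to 350 for Purkinje against Cerebellum, 184 to 213 for Camk2a against Neocortex and 208 to 235 for Gad2 against Neocortex. It gave 160 to 177 for Gad2 against Camk2a, 253 to 295 for Purkinje against Gad2, 34 to 40 list calls and 100 to 113 hairpins.

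edgeR with TMM factors on recovered reads kept 439 miRNAs after its filter. It called 296, 330, 263, 265, 230, 128 and 304 of them in the order of the report, and 431 between any groups.

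A replicate block gave 283, 361, 234, 246, 199, 153 and 287 calls in that order, 452 between any groups, 36 list calls and 112 hairpins; the activity list lost its call for PV against SST (adjusted p = 0.0628). Taken over all groups, no pairing by number was seen. Over 52 pairs of equal number in different groups the median correlation of residuals was 0.015 (range -0.23 to 0.18). Of 19 libraries 8 correlated best with their own number. Equal numbers gave 0.03, 0.07 and 0.05 between Purkinje and Cerebellum, and 0.06, 0.09 and 0.18 between Camk2a and Neocortex. They gave -0.1, -0.23 and -0.1 between Camk2a and Gad2. Pairing between a cell type and its tissue of the same strain is therefore not excluded.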

Other observations

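The hypothesis on PV and Purkinje cells below was formed and tested after the result was seen, and the other values were not tested beyond the comparisons of the report.

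The muscle miRNAs miR-133a and miR-133b were higher in PV than in SST cells and in Purkinje than in Gad2 cells. miR-1 stood at 1849 and 2323 RPM in the PV libraries against 85.2 and 73.6 in the SST libraries, but was lower in Purkinje than in Gad2 cells (269 ± 21.9 against 566 ± 52.2 RPM, n = 3 each). miR-133b stood at 9140 ± 1366 RPM (n = 3) in Purkinje cells. PV and Purkinje cells may share further miRNAs. Of the miRNAs higher in PV than in SST cells, 27 were also higher in Purkinje than in Gad2 cells with TMM factors, against 16.1 expected (one-sided Fisher's exact p = 0.00103). Without those factors 6 were shared against 4.3 expected (one-sided Fisher's exact p = 0.246), so the data cannot tell. Both sets include miR-133a and miR-133b, which prompted the hypothesis. These names may share reads, since their summed reads were near-equal in Purkinje cells (70141 and 72364) but not in PV cells (39055 and 5470). Lower calls overlapped too, 34 against 18.2 expected with TMM factors (one-sided Fisher's exact p = 4.66e-06) and 72 against 45.2 without (one-sided Fisher's exact p = 1.91e-08). Fisher's test takes names as independent, which names of identical values and clustered miRNAs are not, so these p-values may be too small.

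miR-128 set excitatory neurons apart from every other neuron class measured. Its level was 153461 ± 14821 RPM in Camk2a cells, against 9122 ± 3497 in Gad2 (n = 3 each), 2206 ± 216 in Purkinje (n = 3), 1888 ± 155 in PV and 2344 ± 283 in SST cells (n = 2 each). Among Gad2 libraries, replicate 3 held the most miR-128 (13159 RPM against 7018 and 7191) and the most miR-221 (399.9 against 147 and 83.6), both of them high in Camk2a cells. RNA of excitatory neurons in that library could raise both, and the log2 change of miR-221 against Camk2a went from -3.9 to -4.52 without it.

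Several miRNAs moved in opposite directions in Purkinje and Camk2a cells relative to their tissues. miR-218 had log2 changes of -4.69 and 1.16, miR-16 of -3.68 and 1.14, miR-128 of -3.12 and 0.98, and miR-98 of 1.78 and -0.97. Names of miR-219 differed between regions, with miR-219-3p at 114.9 ± 26.5 RPM in Neocortex and 2.52 ± 1.34 in Cerebellum. miR-219-5p stood at 23.3 ± 4.11 and 47.2 ± 15.2. The data also hold miR-219-3p*, so miR-219-3p and miR-219-5p need not be the arms of 1 hairpin. The single value of miR-182 in PV replicate 1, 90.2 RPM against 2.71 in PV replicate 2, was the highest of all libraries.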
